A study of Sus scrofa with 2 samples.

How the data were processed

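RNA-seq was performed on 2 libraries of the PSI clone of pig ileum smooth muscle cells. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra kit. The submitters' processing notes name TopHat2 2.0.12, a spliced read aligner, HTSeq 0.6.1, a read counter, and the pig genome build Sscrofa11.1. The annotation release, the strand setting and the filters are not given in the sources used here. The authors deposited 1 table of FPKM values with a column per library, so replicates were not pooled, and no other scaling was visible: the columns summed to 368640.0 and 367669. FPKM corrects for gene length and library total, so levels of different genes can be set side by side, but a wrong or incomplete gene model changes them. HTSeq by its usual settings drops reads that align to several places or fall in more than 1 gene model, so genes with near-identical copies or overlapping neighbours can be listed too low.

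Because a whole number of reads lies behind each value, the ratio of the 2 columns in low genes takes steps, which gave the ratio of the library totals. The values of 1 read across genes then gave the totals, under which each gene length comes out as a whole number. They were 35176565 and 32217729, and are the numbers the authors divided by, in reads or read pairs. Each gene was assigned the shortest length from 50 to 30000 bp that made both values whole, within 1.2 times the rounding of the deposited digits. This gave whole reads for 100.0% of the 16327 genes above 0, and the recovered length equalled the RefSeq length in 11 of 12 mitochondrial protein genes. Recovered reads are the smallest that fit and can be a fraction of the true ones: they summed to 90.8% and 90.8% of the totals. On simulated libraries of 25880 genes, both totals were recovered exactly, 83.9% of genes received their true reads and the rest received fewer. At 1 FPKM a gene of 2 kb has about 70.4 and 64.4 reads. No length can be recovered for a gene without reads, so no upper limit is given for genes listed at 0. Reads without molecular identifiers are not independent molecules, so statements on sampling noise cover counting error alone.

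Identifiers were paired with symbols through a gene name table, which matched 14857 of 25880 identifiers and 86.4% of those at 1 FPKM or more in both libraries. Coordinates are those of the RefSeq annotation of Sscrofa11.1, matched by symbol. Expression was summarised as log2(FPKM + 1), which compresses values under 1 FPKM. The design holds 1 group, so no test between conditions was possible. A gene was called detected at 1 FPKM or more in both libraries. For each of 34 gene lists, the median over its measured members was placed among 10000 random lists of the same size from all 14856 symbols, and called high from percentile 97.5 and low to 2.5, so about 5% of random lists would be called. The background contains genes silent in any given cell, so lists of widely expressed genes lie high in most cells. The contractile list was also set against each of 11 lists of other cell types by 10000 reassignments of their genes. On 14856 symbols, 7% of 100 simulated random lists of 20 genes were called and 71% of lists raised by 2 log2 units were called high. For the comparison of lists, 7% of 100 random pairs of 17 and 20 genes were called and 87% of those raised by 3 log2 units were called high. The recovered reads of the libraries were compared gene by gene with a two-sided exact binomial test and Benjamini-Hochberg adjustment.

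The lists, the calls and the rule for naming genes were fixed before the data were examined. The rule named every measured contractile marker, the 4 highest members of each other list, members of the other cell type lists with a mean of 10 FPKM or more, the 25 most abundant genes with a symbol, and the 5 largest differences between libraries in each direction among genes with a mean of 5 FPKM or more, and HOX genes with a mean of 1 FPKM or more. Some of these are summarised or not reported here, and further members named for their known role (such as EPCAM, PTPRC, CHRM2, TERT and IL6) were chosen after their values were seen. Alternatives changed the pseudocount, the detection level, the list summary, the random background, the scaling and the contractile markers used, and left out each library. Identifiers without a symbol entered counts and shares but no list. The lists named were smooth muscle contractile, actin cytoskeleton, extracellular matrix, fibroblast, pericyte and vascular mural cell, interstitial cell of Cajal, enteric neuron, enteric glia, intestinal epithelium, endothelium, leukocyte, mesothelium, skeletal muscle, cardiac muscle, muscle transcription regulators, contraction signalling, calcium handling and ion channels, neurotransmitter and hormone receptors, growth factor receptors, pattern recognition, cytokines and chemokines, interferon-stimulated, antigen presentation, receptors used by viruses of pigs, cell cycle, growth arrest and telomere, HOX, integrins, matrix proteases and inhibitors, YAP and TGF-beta target, immediate early, glycolysis, cholesterol synthesis, mitochondrially encoded. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.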

Results

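The data set described PSI, a clone of smooth muscle cells derived from pig ileum, the last part of the small intestine. The cells were grown in DMEM with 10% fetal bovine serum, and how the RNA was selected for sequencing is not given in the sources used here. RNA-seq libraries were sequenced in duplicate from the clone, giving 1 group of 2 libraries with no untreated, tissue or other-cell comparison. The labels gave no separate cultures or animals for the duplicates, so the SD printed beside a mean measures the spread between these 2 libraries, which may be technical. Expression was measured as FPKM, fragments per kilobase of gene length, scaled to the library total, for 25880 gene identifiers, of which 14857 were paired with a symbol. The library totals recovered from the steps of the FPKM values were 35176565 for replicate 1 and 32217729 for replicate 2, so 1 read in a gene of 1 kb was worth 0.0284 and 0.0310 FPKM, respectively. Means are over both libraries, as mean ± SD with n = 2, and a gene listed at 0 in a library is given per library. With 1 group there is no test of a difference between conditions, and percentiles of gene lists describe these libraries.

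The duplicate libraries gave nearly the same profile. Among genes with a symbol and a mean of 5 FPKM or more, the largest difference in each direction was that of a small nucleolar RNA gene with few reads, SNORD104 and SNORD45A. SNORD104 had 5.77 FPKM in replicate 1 and 13.5 in replicate 2, from 14 and 30 recovered reads. SNORD45A, SNORD93, SNORD79 and SNORD21 were higher in replicate 1, with 24 and 13, 50 and 29, 79 and 50 and 40 and 26 reads, respectively. The other genes among the 5 largest differences in each direction were protein-coding genes with more reads: DNAJC4, a co-chaperone, was higher in replicate 1 with 441 and 290 reads, and PTPN18, CCDC28B, WDR54 and CDPF1 were higher in replicate 2, PTPN18 with 322 and 406 reads. Across all genes, Pearson's r of log2(FPKM + 1) was 0.9984 and Spearman's rho was 0.972, where genes are not independent replicates. Of the 10738 genes with a mean of 1 FPKM or more, 71 were over 2-fold apart. The median coefficient of variation of these genes was 2.62%. The recovered reads differed by more than sampling noise: the mean squared deviation from binomial sampling was 1.75 per gene over 16327 genes, where sampling alone gives 1, and an exact binomial test separated the libraries at 182 genes with a Benjamini-Hochberg adjusted p under 0.05. Of the genes named above, only DNAJC4 and PTPN18 passed that test. Abundant transcripts passed it in both directions, such as COX1 (9223 and 8604 FPKM in replicates 1 and 2) and COL1A1 (3588 and 3629). The test compares the libraries and no condition. The duplicates were counted as 2 libraries, and a spread beyond counting error does not show that they come from separate cultures.

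**Figure D1:**
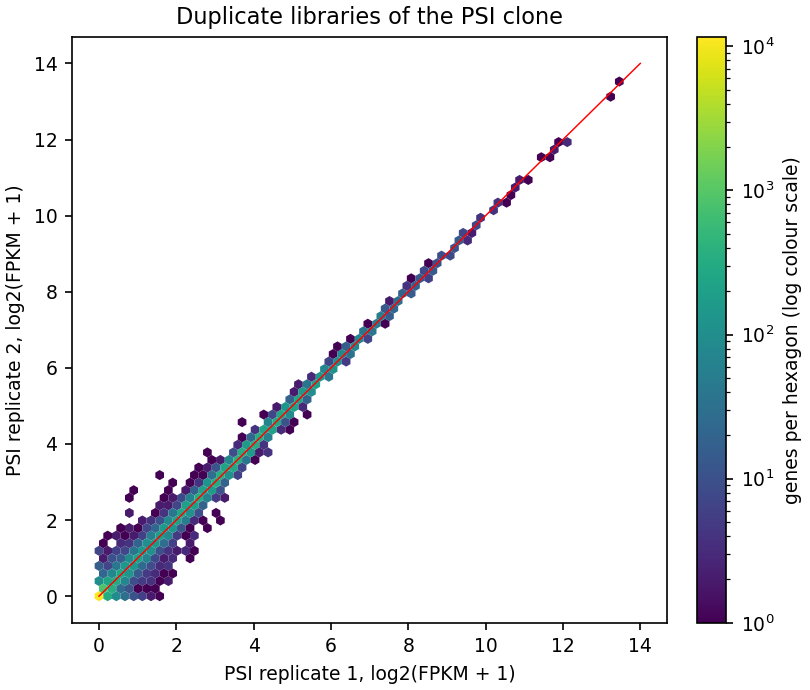
Each hexagon holds genes at a given log2(FPKM + 1) in replicate 1 (x axis) and replicate 2 (y axis) of the PSI clone, coloured by the number of genes on a log scale, with the line of equality in red. The genes follow the line (Pearson's r 0.9984) and spread mainly at low FPKM.

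The most abundant named transcripts of the clone were those of the actin cytoskeleton, the extracellular matrix and the mitochondrial genome. COX1, a mitochondrially encoded cytochrome oxidase subunit, had 8913 ± 437 FPKM (SD, n = 2). The mitochondrial genes COX3 (4137 ± 181), ATP6 (1724 ± 58.9), COX2 (1561 ± 19.3) and ND5 (1000.1 ± 9.07) were also among the 25 highest. The actin system contributed ACTG1 (4072 ± 73.5), ACTB (1861 ± 9.76), TMSB10 (3846 ± 47.8), TMSB4X (2097 ± 100.3), MYH9 (1184 ± 11.2) and CFL1 (1166 ± 31.1), together with the intermediate filament gene VIM (1951 ± 26.2). The secreted matrix contributed COL1A1 (3608 ± 29.0), COL1A2 (3554 ± 20.5), THBS1 (3007 ± 5.53), SPARC (2935 ± 22.5), FN1 (1343 ± 20.2) and COL5A1 (946 ± 15.2). Others were TPT1, ANXA2, RPLP0, RPS16, TUBA1B and UBB, between 936 and 1299 FPKM. In all, 10583 identifiers reached 1 FPKM in both libraries, 40.9% of the table, and 9553 were listed at 0 in both. The 10 most abundant genes held 13.6% and 13.5% of the summed FPKM of replicates 1 and 2, and the 100 most abundant held 32.4% and 32.0%.

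The series title names an enteric smooth muscle line, so the question was which markers of differentiated smooth muscle the clone expressed. The markers ranged from abundant genes to genes listed at 0. ACTA2, the smooth muscle alpha-actin, had 693 ± 11.8 FPKM (SD, n = 2), and ACTG2, the gamma-actin of visceral smooth muscle, had 479 ± 15.0. CSRP1 had 363 ± 0.441 and CNN1, the actin-binding protein calponin, had 254 ± 1.02. NEXN (60.7 ± 0.0944), LMOD1 (45.1 ± 0.0997) and SMTN (39.6 ± 1.14) stood at intermediate levels, each from over 1000 reads per library. TAGLN, which encodes an actin-associated protein, had 5.46 ± 0.175 FPKM from 265 and 254 reads, and DES, the muscle intermediate filament desmin, had 2.90 ± 0.231 from 79 and 81 reads. The identifier paired with MYH11, the smooth muscle myosin heavy chain, had 0.491 ± 0.0433 FPKM from 106 and 110 reads. This pairing was not checked by position. SYNPO2 had 0.148 ± 0.0520, HSPB6 0.0967 ± 0.0402 and PDLIM3 0 in replicate 1 and 0.0350 in replicate 2. PCP4, KCNMB1 and MYOCD, the last encoding the smooth muscle coactivator myocardin, were listed at 0 in both libraries. SYNM, PLN and CASQ2 had no identifier with that symbol in the table and were not analysed here.

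On the Sscrofa11.1 assembly, the RefSeq annotation places ACTA2 on chromosome 14 from 100868145 to 100886732, ACTG2 on chromosome 3 from 69097366 to 69121542 and CNN1 on chromosome 2 from 70183370 to 70190756. It places TAGLN on chromosome 9 from 44561756 to 44567385, DES on chromosome 15 from 121428539 to 121435426 and MYH11 on chromosome 3 from 7002667 to 7143093. The identifiers of ACTA2, ACTG2, TAGLN and MYH11 in the table were ENSSSCG00000010447, ENSSSCG00000008294, ENSSSCG00000015073 and ENSSSCG00000000146. All 6 genes are protein-coding, and each FPKM value covers the gene's whole counted model rather than a single exon. Table values and coordinates were joined by symbol alone, and the pairing of identifiers with RefSeq genes was not checked by position, so the value given for MYH11 may belong to another gene. The MYH11 identifier is numbered next to that of MYH9, ENSSSCG00000000145, a gene that RefSeq places on chromosome 5. Of the contractile list, 10 of the 17 measured members reached 1 FPKM in both libraries. The list's median was 2.69 on the log2(FPKM + 1) scale, at percentile 67.5 of random lists, which did not set it apart from random lists of 17 genes. The mean over the same members was 3.67, at percentile 98.99, and without the 3 members at 0 the median was at percentile 99.98, both called high, as was the median among genes of 0.1 FPKM or more (percentile 100). With a pseudocount of 0.1 the mean was at percentile 94.3 and was not called. The settings without members at 0 and with genes of 0.1 FPKM or more kept 14 and 12 members. They left out members by the level being tested, with the random background filtered alike. Their calls therefore describe the kept members and do not show that the whole list was high. Values near 0 need care in this table, since 8 of 106 genes used by every or nearly every cell, among them RPL29 and TPI1, were also under 1 FPKM. Low values above 1 FPKM need care too. PFN1 (6.37 FPKM) and MYL6 (5.95) lay below the other 21 measured actin cytoskeleton genes, each at a mean of 10 FPKM or more. TAGLN lay at a level similar to theirs and was the middle member that set the contractile median. The RefSeq models of MYH11, SYNPO2, KCNMB1, PDLIM3 and MYOCD overlap another gene and their values are therefore uncertain, as are those of NEXN and LMOD1.

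**Figure D2:**
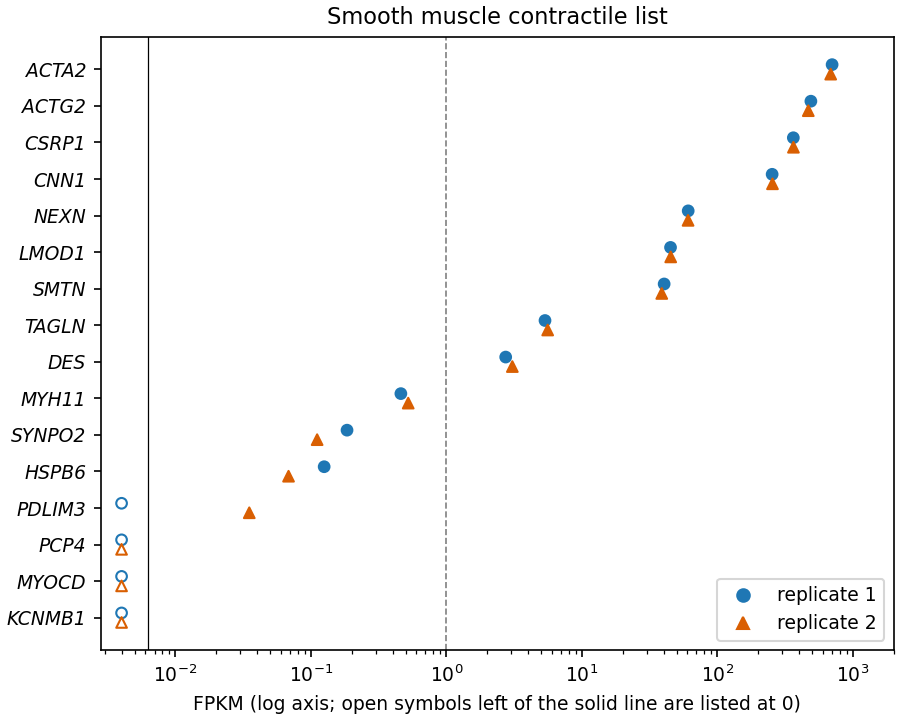
Points give the FPKM of the smooth muscle contractile markers named in the text in replicate 1 (circles) and replicate 2 (triangles) on a log axis, with values listed at 0 drawn as open symbols left of the solid line and 1 FPKM as a dashed line. Markers range from ACTA2 at 702 and 685 FPKM to PCP4, MYOCD and KCNMB1 at 0 in both libraries. The values drawn for MYH11 may belong to another gene.

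Markers of most other cells of the ileum wall, and of skeletal and cardiac muscle, were close to 0, with a few abundant exceptions. In the intestinal epithelium list, 13 of 24 measured members were listed at 0, among them CDH1, VIL1 and MUC2, EPCAM had 0 in replicate 1 and 0.00748 in replicate 2 FPKM, and APOA1, an apolipoprotein, had 13.8 ± 0.377 (SD, n = 2). In the leukocyte list, PTPRC and CD3E were listed at 0, and the highest member was CD14, the lipopolysaccharide co-receptor, at 2.29 ± 0.0775, ahead of CORO1A (1.57 ± 0.120), CD68 (1.24 ± 0.102) and CD74 (0.894 ± 0.00561). Endothelial CDH5, KDR and TIE1 were listed at 0, PECAM1 had 1.76 ± 0.231, ERG 0.261 ± 0.0127 and ESAM 0.195 ± 0.173, and FLT1, a receptor of vascular endothelial growth factors, had 34.4 ± 1.55. Neuronal SNAP25 (0 in replicate 1 and 0.0172 in replicate 2) and STMN2 (0 in replicate 1 and 0.0276 in replicate 2) were near 0 and RET had 0.665 ± 0.0171, whereas UCHL1, a ubiquitin hydrolase abundant in neurons, had 238 ± 1.92, HAND2, a transcription factor of mesenchyme and autonomic neurons, had 62.1 ± 0.477, and TUBB3 had 29.2 ± 0.365. In the glia list SOX10 had 0.139 ± 0.00229, MIA 0.287 ± 0.118, FOXD3 3.11 ± 0.184 and GFRA3, a neurotrophic factor receptor, 12.5 ± 0.803. Among mesothelial markers, WT1 had 4.75 ± 0.0715, KRT7 2.27 ± 0.348, ALDH1A2 0.224 ± 0.0139 and GPM6A 0.0282 ± 0.00175. Of the skeletal muscle genes, MYOD1, MYOG and PAX7 were listed at 0, and TNNT1 (3.31 ± 0.253), TNNC2 (1.18 ± 0.397), ACTA1 (0.965 ± 0.0337) and MYF6 (0.0120 ± 0.00633) were the highest. Of the cardiac genes, NPPB, which encodes brain natriuretic peptide, had 11.3 ± 0.545, TBX20 3.49 ± 0.0858, RYR2 0.858 ± 0.0430 and MYBPC3 0.136 ± 0.00118.

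Markers of the mesenchymal neighbours of smooth muscle were more mixed. In the fibroblast list, S100A4 had 408 ± 11.9 FPKM (SD, n = 2), and SFRP2, a secreted Wnt modulator, had 47.5 ± 0.143, followed by SFRP1 (7.39 ± 0.479) and TCF21 (3.90 ± 0.197). PDGFRA had 2.24 ± 0.0149, DCN 2.20 ± 0.445, FAP 0.156 ± 0.0254 and CD34 0 in replicate 1 and 0.00550 in replicate 2. Among pericyte and vascular mural cell markers, CSPG4, a cell surface proteoglycan, had 101 ± 2.06, PDGFRB 44.3 ± 1.30, ADGRA2 35.3 ± 0.0960, GJC1 30.3 ± 0.255 and MCAM 14.5 ± 0.648, whereas RGS5 had 0.00511 in replicate 1 and 0 in replicate 2 and ABCC9 was listed at 0. In the list for interstitial cells of Cajal, the gut pacemaker cells, the highest member was KITLG (18.9 ± 0.0622). It encodes the ligand of the receptor KIT and is not itself a marker of these cells. ETV1 had 14.3 ± 0.353, SLC4A4 3.64 ± 0.0657, ANO1 0.792 ± 0.0387 and KIT 0.573 ± 0.135.

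Across the 11 lists for other cell types, 185 markers were measured, 36 reached 1 FPKM in both libraries and 16 had a mean of 10 or more. The contractile median lay above the median of each of these lists. On the log2 scale the difference was 2.69 (percentile 99.97) over the epithelial list, 2.69 (percentile 100) over skeletal muscle, 2.66 (percentile 100) over leukocytes, 2.67 (percentile 99.67) over cardiac muscle, 2.67 (percentile 98.83) over neurons, 2.66 (percentile 99.67) over mesothelium, 2.63 (percentile 99.75) over endothelium, 2.57 (percentile 99.44) over glia and 2.495 (percentile 98.97) over fibroblasts, where the percentile is that among 10000 reassignments of the same genes to the lists. It was 2.04 (percentile 90.0) over interstitial cells of Cajal and 1.41 (percentile 63.7) over pericytes, inside the range of reassigned lists. Without the 5 contractile markers that cultured fibroblasts and myofibroblasts also express (ACTA2, TAGLN, CNN1, CSRP1 and NEXN), the difference over fibroblasts was 0.19 (percentile 57.1), that over pericytes turned to -0.89 and that over interstitial cells of Cajal to -0.26. Of the 9 calls, only that over the epithelial list (percentile 99.92) held without these markers. The 8 lost calls stood at percentiles from 57.1 (fibroblasts) to 96.96 (skeletal muscle) and 97.455 (endothelium). The 5 removed markers were TAGLN, which set the contractile median, and genes above it, so the median had to fall. It then lay between MYH11 and SYNPO2, whose values are uncertain. The lost calls therefore cannot show whether the differences depend on markers shared with fibroblasts. Against random lists, the fibroblast (percentile 1.95), neuron (0.17), epithelium (0), endothelium (0.77), leukocyte (0.08), mesothelium (2.38), skeletal muscle (0) and cardiac muscle (0.30) lists were low. Most matrix genes that fibroblasts share with smooth muscle stood in the extracellular matrix list instead, which was high (percentile 100). The low fibroblast call therefore covers the other fibroblast markers alone. The glia (3.1), pericyte (20.5) and interstitial cell of Cajal (14.4) lists were not called. By the mean the glia list was low with a pseudocount of 1 or 0.1 (percentiles 0.04 and 0.04), and the interstitial cell list was low with a pseudocount of 1 (percentile 2.48, or 3.74 and not called with a pseudocount of 0.1). Without replicate 2 the glia list was low (percentile 2.48), and without replicate 1 or replicate 2 the mesothelium list was not (percentiles 2.71 and 2.95). Against random lists from the whole table, where many identifiers without a symbol were at 0, none of the 8 low calls by the median held. Among genes of 0.1 FPKM or more, the neuron (32.3), mesothelium (13.9), skeletal muscle (7.2) and cardiac muscle (6.2) lists were not called, the contractile list's differences over these 4 were not called either, and the glia list was low (0.24). Without members at 0, skeletal muscle was not called (3.6) and glia was low (0.23).

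**Figure D3:**
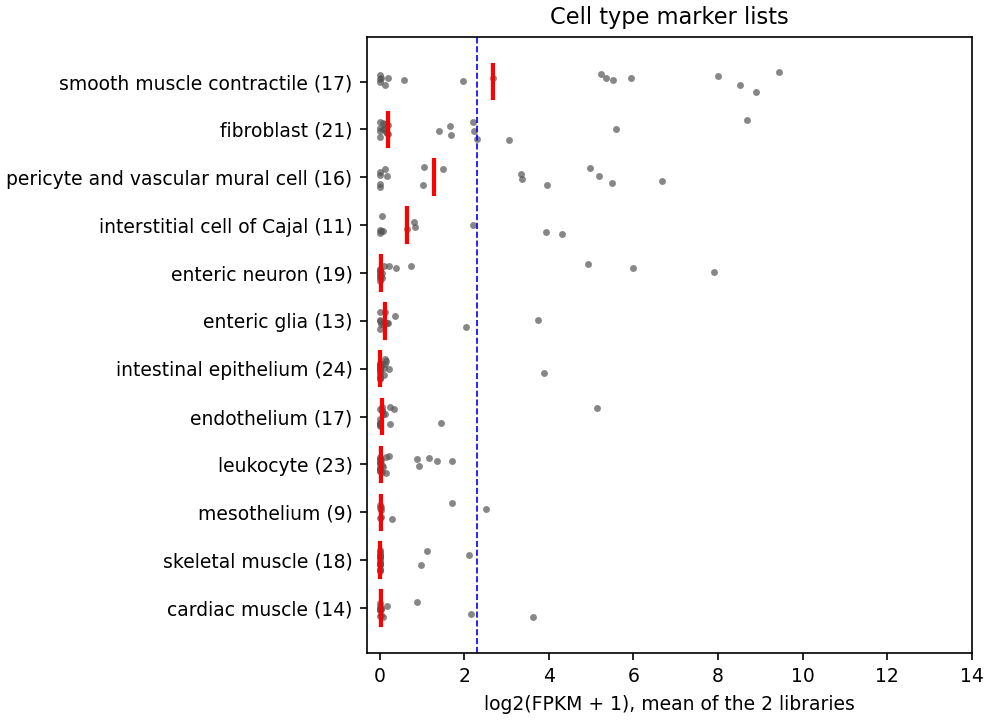
Each grey point is a marker gene at its log2(FPKM + 1), averaged over the 2 libraries, in the list named on the y axis with its number of measured members, and vertical spread within a list is for legibility alone. Red bars mark list medians, highest for the contractile list at 2.69, and the blue dashed line marks the median of all genes with a symbol, 2.29.

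Most genes of the broader actomyosin machinery and of the signalling that drives contraction were expressed. All 23 measured actin cytoskeleton genes reached 1 FPKM in both libraries, led by ACTG1, VIM, ACTB and MYH9. FLNA had 868 ± 6.66 FPKM (SD, n = 2), CALD1, the actin regulator caldesmon, 456 ± 1.68, TPM1 427 ± 17.2, MYL9, the regulatory myosin light chain of smooth muscle, 123 ± 0.271, and MYLK, the myosin light chain kinase, 29.9 ± 0.163. The list's median was 7.93 on the log2(FPKM + 1) scale, at percentile 100 of random lists. Of the contraction signalling genes, 27 of the 30 measured reached 1 FPKM, at percentile 100. CALM2, which encodes calmodulin, had 382 ± 5.92, GNAI2 177 ± 1.504 and RHOA 143 ± 5.71. ROCK1 had 29.8 ± 0.621 and ROCK2 26.7 ± 0.744, the soluble guanylate cyclase subunit gene GUCY1B1 29.2 ± 1.06, PRKG1 4.13 ± 0.364 and PPP1R14A 0.153 ± 0.00204. Such genes are active in most adherent cells, so their rank is not specific to muscle.

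Transcription regulators of muscle and gut mesenchyme were present at moderate levels with several members at 0. PRRX1, a mesenchymal homeobox gene, had 61.9 ± 1.57 FPKM (SD, n = 2), SRF, the serum response factor that binds smooth muscle promoters, 47.6 ± 0.900, TEAD3 42.8 ± 1.498 and TEAD1 37.4 ± 0.576. The SRF coactivator MRTFA had 26.03 ± 0.809 and MRTFB 3.82 ± 0.173. FOXF1, a regulator of gut mesenchyme, had 4.996 ± 0.189, NKX2-3 0.589 ± 0.171 and GATA6 0.457 ± 0.184, whereas MYOCD, BARX1, FOXF2 and GATA4 were listed at 0. In all, 21 of the 27 measured reached 1 FPKM, and the list was not set apart from random lists (percentile 73.0), but was called high against the whole table (99.07).

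Ion channel and receptor genes differed widely. GJA1, a gap junction connexin, had 199.8 ± 2.86 FPKM (SD, n = 2), ATP2A2, the calcium pump of the sarcoplasmic reticulum, 60.2 ± 0.0800, ATP2B4 60.1 ± 0.319 and GJC1 30.3 ± 0.255. KCNMA1, the large-conductance potassium channel, had 0.474 ± 0.0807, and CACNA1C was not analysed here because no identifier carried its symbol. Of the calcium and channel genes, 20 of the 34 measured reached 1 FPKM (percentile 34.9). Receptors by which nerves and hormones act on gut muscle were mostly near 0: 9 of the 35 measured reached 1 FPKM, and the list was low at percentile 0.18, a call that ended against the whole table (percentile 38.9). The muscarinic receptor genes CHRM2 and CHRM3 were listed at 0 in both libraries, TACR1 had 0 in replicate 1 and 0.00526 in replicate 2 and TACR2 0.0715 ± 0.00825. The highest were the sphingosine phosphate receptor S1PR2 (27.3 ± 1.26), the angiotensin receptor AGTR1 (21.8 ± 1.24), the nucleotide receptor P2RY2 (19.4 ± 1.09) and the prostaglandin receptor PTGFR (6.74 ± 0.314). Of the growth factor receptors, 22 of the 29 measured reached 1 FPKM and the list was high (percentile 99.77, or 97.48 and not called among genes of 0.1 FPKM or more), led by AXL (147 ± 2.86), TGFBR2 (84.9 ± 0.0735), IGF2R (45.8 ± 0.442) and PDGFRB (44.3 ± 1.30).

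The clone expressed matrix, adhesion and matrix remodelling genes at high levels. Of the extracellular matrix list, 31 of the 34 measured reached 1 FPKM, and the list held 5.52% ± 0.0341 (SD, n = 2) of the summed FPKM. The list's median was 7.26 on the log2(FPKM + 1) scale, at percentile 100 of random lists. Fibroblasts express these matrix genes as well as smooth muscle cells do, so their level does not tell the cell types apart. Besides the genes above, COL3A1 had 763 ± 7.43 FPKM and TNC, the matrix protein tenascin-C, 608 ± 3.45, whereas LUM had 1.63 ± 0.0280, MGP 0.536 ± 0.0143 and FBLN1 0.0793 ± 0.0364. Of the integrin and adhesion genes, 19 of the 25 measured reached 1 FPKM (percentile 99.87), led by ITGB1 (650.1 ± 8.41), FERMT2 (159.6 ± 1.70), ITGA5 (135 ± 0.585) and ILK (114 ± 1.71), and ITGA8, an integrin of mesenchymal and smooth muscle cells, had 71.6 ± 0.639. Of the proteases and inhibitors, 19 of the 25 measured reached 1 FPKM (percentile 99.56), among them SERPINE2 (708 ± 7.10), MMP14 (150.2 ± 0.471) and TIMP1 (143 ± 3.69). Genes known to be raised by YAP or TGF-beta signalling reached 1 FPKM in 20 of the 21 measured cases (percentile 100). Among them were CCN2 (295 ± 2.28), F3 (275 ± 4.61) and CCN1 (271 ± 1.08).

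Genes of proliferating cells were abundant. Of the cell cycle list, 26 of the 28 measured reached 1 FPKM in both libraries, at percentile 100. The exceptions were CDK2 (0.163 FPKM) and CDC20, listed at 0 in both libraries. Neither was among the 106 widely used genes checked for low values. UBE2C, a ubiquitin-conjugating enzyme of mitosis, had 167 ± 5.25 FPKM (SD, n = 2), PLK1 74.1 ± 0.116, MCM6 71.9 ± 0.872 and MCM5 70.3 ± 0.834, and TOP2A 33.0 ± 0.0929. Genes of growth arrest and telomere maintenance reached 1 FPKM in 24 of the 25 measured cases (percentile 99.71, or 95.2 and not called among genes of 0.1 FPKM or more). Among them were CDKN2A, which encodes cell cycle inhibitors, at 199.9 ± 5.49, MYC at 123 ± 0.948 and LMNB1 at 66.5 ± 0.000627. CDKN1A had 56.3 ± 0.0840. TERT, the catalytic subunit of telomerase, had 0.0175 ± 0.00109 FPKM from 2 and 2 recovered reads, too few to give its level.

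Interferon-stimulated genes stood out among the immune lists. Of the interferon-stimulated list, 20 of the 21 measured reached 1 FPKM in both libraries and none was at 0. IFI6 had 638 ± 6.89 FPKM (SD, n = 2), MX1, an antiviral GTPase, 358 ± 8.62, ISG15, a ubiquitin-like modifier, 216 ± 5.36, and IFIT1 90.8 ± 0.528. The list's median was 5.54 on the log2(FPKM + 1) scale, at percentile 100 of random lists. Of the pattern recognition genes, 20 of the 32 measured reached 1 FPKM, without standing apart (percentile 67.1) except against the whole table, where the list was called high (99.36). RIGI, a sensor of viral RNA that is itself raised by interferon, had 88.6 ± 0.452, RELA 63.1 ± 0.541, IRAK1 45.9 ± 0.0742 and IRF3 28.2 ± 0.747. TLR3, the receptor of double-stranded RNA, had 19.1 ± 0.527, TLR4 0.541 ± 0.102 and TLR2 0.251 ± 0.0156, and the other 7 toll-like receptor genes were each under 1 FPKM. Of the cytokine genes, 14 of the 26 measured reached 1 FPKM (percentile 57.9, or 97.99 and called high against the whole table). IL11, a cytokine of mesenchymal cells, had 259 ± 3.42, CCL2, a monocyte attractant, 226 ± 0.882, TGFB2 75.0 ± 2.24 and MIF 61.9 ± 1.92, whereas IL6 had 4.04 ± 0.0137 and CXCL12 0.0104 in replicate 1 and 0 in replicate 2. Of the antigen presentation genes, 6 of the 12 measured reached 1 FPKM (percentile 20.02), led by TAP2 (65.3 ± 1.32), TAPBP (59.9 ± 1.49), TAP1 (38.7 ± 0.923) and CD86 (7.89 ± 0.165). The MHC genes of pigs are a polymorphic family whose reads can be shared, and 12 of the 23 listed members were measured under their symbol.

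Host genes used by pig viruses for entry reached 1 FPKM in 19 of the 28 measured cases, and the list was high at percentile 99.89. The highest were broadly expressed genes: HSPA8 (862 ± 20.4 FPKM, SD, n = 2), ITGB1 (650.1 ± 8.41), RPSA (372 ± 4.11) and CD151 (202 ± 0.186). The scavenger receptor gene CD163, used by the porcine reproductive and respiratory syndrome virus, was listed at 0 in both libraries and SIGLEC1 had 0.135 ± 0.0424. ANPEP, the aminopeptidase used by transmissible gastroenteritis virus, had 3.53 ± 0.238.

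**Figure D4:**
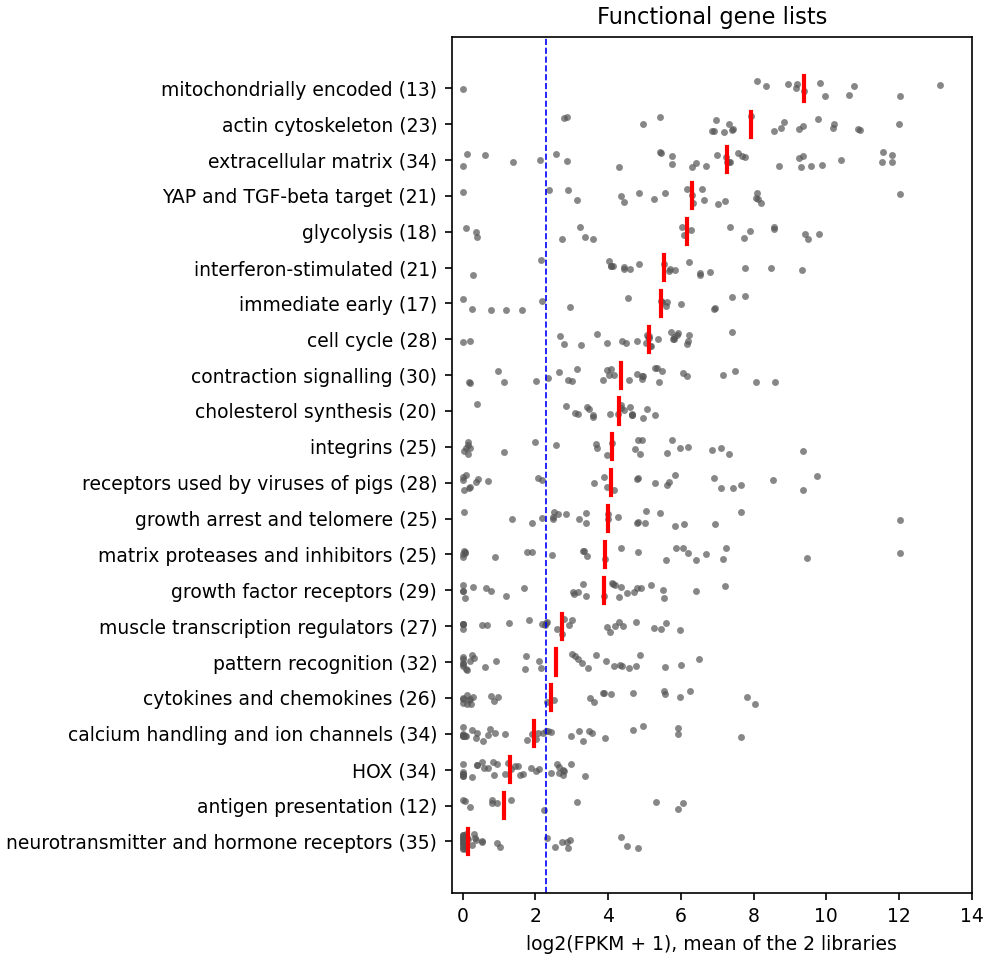
Each grey point is a gene at its log2(FPKM + 1), averaged over the 2 libraries, in the functional list named on the y axis with its number of measured members, and vertical spread within a list is for legibility alone. Red bars mark list medians, from 9.38 for the mitochondrially encoded genes to 0.14 for the neurotransmitter and hormone receptors, and the blue dashed line marks the median of all genes with a symbol, 2.29.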

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

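The most abundant identifier of the table had no symbol and so entered none of the gene list comparisons. It had 11503 ± 375 FPKM (SD, n = 2), above COX1 at 8913 ± 437, and stands out as signal outside the named genes. Its recovered reads, the smallest that fit, were 385051 and 369283. Identifiers without a symbol held 16.4% and 16.6% of the summed FPKM of replicates 1 and 2, and 105 of 11023 had a mean of 100 FPKM or more. What they encode was not analysed here.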

How the results depend on the processing

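The omission of members listed at 0 and the use of recovered reads were chosen after seeing the data. Pearson's r between the libraries was 0.9946 and 0.9852 with pseudocounts of 0.1 and 0.01, 0.9970 in genes with a mean FPKM of 1 or more, 0.9975 in genes above 0 and 0.9973 after rescaling to TPM. The 71 genes over 2-fold apart became 2 at a mean FPKM of 5 or more and 220 after rescaling to TPM, which lowers the threshold in FPKM. The exact binomial test of recovered reads separated 182 genes. The count of detected genes ranged from 7666 at 5 FPKM to 13025 at 0.1 FPKM, and was 12228 with at least 10 recovered reads. Without mitochondrially encoded and ribosomal protein genes, the 10 and 100 most abundant genes held 12.3% and 29.4%. List percentiles kept their call under TPM scaling and a protein-coding background. With the mean in place of the median, percentiles that became calls were smooth muscle contractile (98.99), interstitial cell of Cajal (2.48), enteric glia (0.04) and HOX (0.24), of which enteric glia alone (0.04) was also called with a pseudocount of 0.1. With genes of a mean FPKM of 0.1 or more, calls were gained for smooth muscle contractile (100), enteric glia (0.24) and HOX (0.03), lost for enteric neuron (32.3), mesothelium (13.9), skeletal muscle (7.2), cardiac muscle (6.2), growth factor receptors (97.48) and growth arrest and telomere (95.2), and uncalled lists crossed the middle for pericyte and vascular mural cell (56.8) and muscle transcription regulators (25.3), with fewer genes tested. Random lists from the whole table, which holds many silent identifiers, ended the call for fibroblast (47.6), enteric neuron (21.7), intestinal epithelium (3.2), endothelium (30.5), leukocyte (21.5), mesothelium (30.9), skeletal muscle (4.4), cardiac muscle (19.8) and neurotransmitter and hormone receptors (38.9), gave a call for muscle transcription regulators (99.07), pattern recognition (99.36) and cytokines and chemokines (97.99) and moved uncalled pericyte and vascular mural cell (80.3), interstitial cell of Cajal (66.0), calcium handling and ion channels (96.7), antigen presentation (74.2) and HOX (89.5) across the middle. Without members at 0, smooth muscle contractile (99.98) and enteric glia (0.23) were called and skeletal muscle (3.6) was not. Settings that leave out members by their level describe the kept members alone. With replicate 1 or 2 left out, enteric glia lay between 2.48 and 3.7, called without replicate 2, and mesothelium between 2.71 and 2.95, uncalled without either, and no other list changed its call. The contractile list's log2 difference without the 5 shared markers lost its call against fibroblast (0.19), enteric neuron (0.36), enteric glia (0.27), endothelium (0.33), leukocyte (0.35), mesothelium (0.36), skeletal muscle (0.39) and cardiac muscle (0.36) and turned over against pericyte and vascular mural cell (-0.89) and interstitial cell of Cajal (-0.26). With members of 0.1 FPKM or more it lost its call against enteric neuron (2.61), mesothelium (3.73), skeletal muscle (4.32) and cardiac muscle (3.90), where 3 to 6 members remained. Against interstitial cells of Cajal it was called by the mean with a pseudocount of 1 (2.497), not with 0.1 (percentile 96.3). It was also called without members at 0 (4.55). Where no reason is given, the cause was not tested. No paired analysis was possible because there is a single group. Depth limits low values: 3 reads in a gene of 1 kb give 0.0853 and 0.0931 FPKM in replicates 1 and 2.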

Other observations

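Expressed HOX genes, which mark position along the body axis, ran from group 2 to group 11. HOXD8 had 9.36 ± 0.363 FPKM (SD, n = 2), HOXC8 6.96 ± 0.285, HOXB4 5.89 ± 0.411, HOXD9 5.82 ± 0.638 and HOXB3 5.81 ± 0.201. HOXB6, HOXB2, HOXC6, HOXC9, HOXA7, HOXD3, HOXA3, HOXA10, HOXD4, HOXA5, HOXA2, HOXB7, HOXA11 and HOXA9 lay between 1.24 and 5.31, the last of these with 1.24 ± 0.0153. HOXA11, the only group 11 gene at 1 FPKM or more, had 1.40 ± 0.321 from 147 and 97 reads, and HOXD11 had 0.321 ± 0.0843. HOXC11, HOXC12, HOXD12, HOXB13 and HOXC13 were listed at 0 in both libraries. HOXA13 and HOXD13 had no identifier with that symbol and were not analysed here, so the posterior end of the range is uncertain. In all, 19 of the 34 measured members reached 1 FPKM, and the list was at percentile 12.5 of random lists by its median, not called. It was low by the mean with a pseudocount of 1 (0.24) and among genes of 0.1 FPKM or more (0.03), and stood at 89.5 against the whole table, not called.

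Glycolytic, sterol and early response genes were widely expressed. Of the glycolysis list, 15 of the 18 measured reached 1 FPKM (percentile 100), led by GAPDH (894 ± 6.63 FPKM, SD, n = 2), ENO1 (716 ± 6.24), PKM (687 ± 9.59) and LDHA (380.1 ± 6.65). Of the cholesterol synthesis list, 19 of the 20 measured reached 1 FPKM (percentile 99.93), among them MSMO1 (32.4 ± 0.673), SREBF2 (30.4 ± 0.444) and MVD (24.2 ± 0.155). Of the immediate early list, 14 of the 17 measured reached 1 FPKM (percentile 100), with IER3 at 216 ± 10.4, KLF6 at 169 ± 1.49, MYC at 123 ± 0.948 and JUN at 120.0 ± 5.08, whereas FOS had 2.12 ± 0.0535. The mitochondrially encoded genes held 5.75% ± 0.213 of the summed FPKM (percentile 100). ATP8 was listed at 0, and its reading frame overlaps that of ATP6.

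The tests on interferon-stimulated genes and on neuron markers were chosen after the levels were seen. The design holds 1 group, so no biological difference between groups was tested as an explanation.

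Interferon-stimulated genes were high at percentile 100 while IFNB1, the beta interferon gene, had 0.0783 ± 0.0325 FPKM from 2 and 1 reads. RNA from leukocytes is argued against, because the leukocyte list was at percentile 0.08 and PTPRC was listed at 0. Interferon made by the clone itself may still account for it: the highest of the 6 type I and III interferon genes with a symbol had 0.0783 FPKM, but RefSeq lists 33 such symbols in pigs, many near-identical, and most were not measured under a symbol. The interferon receptor genes IFNAR1 (21.2 FPKM) and IFNAR2 (20.05) were expressed. Viral or serum triggers were not tested.

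UCHL1, HAND2 and TUBB3 were abundant although they stood in the neuron list. The highest of the other 16 measured neuron markers, RET, had 0.665 FPKM, with 6 of them listed at 0. UCHL1, HAND2 and TUBB3 were set apart as the only 3 of the list at 1 FPKM or more in both libraries. Low values of the rest followed from that choice, so they cannot decide on RNA from neurons in the cultures. Expression of the 3 genes by the clone stays open as a hypothesis and was not tested further.

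Some genes that every or nearly every cell uses were listed near 0: 8 of 106 ribosomal protein, glycolysis, sterol and actin genes were under 1 FPKM. They were RPL29 and RPS27A, listed at 0, and RPS21 (0 in replicate 1 and 0.244 in replicate 2), RPS2 (0.523), TPI1 (0.324), FDPS (0.315), LDHB (0.0679) and ENO2 (0.302), the last of which is most abundant in neurons. The other genes of the set had a median of 12394 recovered reads in the smaller library. They were taken at 1 FPKM or more, so this median could hardly be small and does not test for too few reads. At 1 FPKM a gene of 2 kb has about 70.4 and 64.4 reads in replicates 1 and 2, so depth allowed that level to be seen. Overlap with a neighbouring RefSeq gene was seen in 2 of 7 of them with a single RefSeq match and 21 of 94 others (one-sided Fisher's exact test, p = 0.503), and ribosomal protein genes, which have many processed copies, were low in 4 of 45 cases against 4 of 61 (p = 0.463). With 8 low genes, neither lost reads in overlapping models nor reads shared between copies could be shown or excluded. Wrong or incomplete gene models and truly low expression were not tested.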
